A study of Mus musculus with 18 samples.

How the data were processed

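The data are 18 arrays of 2 colours, with probes for mouse transcripts, hybridised with mouse embryonic stem cell RNA. Per the labels, the sample was labelled with Cy3 and a universal mouse reference RNA, pooled from cell lines, with Cy5, from 2.5 μg of total RNA each, and the arrays were scanned at 100% photomultiplier gain for Cy3 and 10% for Cy5 at 5 μm. Per the file headers, the deposited scanner output was made with Agilent Feature Extraction 9.5.1.1. It gives the intensity of every spot in each channel as a mean signal with a local background median, processed signals that the software background-subtracted and dye-normalised, and a log10 ratio of Cy5 over Cy3. That ratio is reference over sample, so its sign was turned here, and every log2 value below is sample over reference. The authors also deposited a value table of 25030 probes on a log10 scale. On every array, 100% of its probes lay within 0.001 of the log10 ratio of the processed signals, sample over reference, once each probe was centred over the arrays. Its direction and scale are therefore settled, and the constant added to each probe stays unknown. The column medians of that table lie between 2.33 and 2.36. Per the series description, the submitters tested with NIA Array Analysis at a false discovery rate of 0.05 and a 2-fold change.

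Cultures of Oct4VP2 were plated at 250000 cells and those of the other lines at 200000, per the labels. The labels describe the Oct4 cultures with LIF in other terms than the remaining Oct4 cultures (a knock-in, without mention of tetracycline or puromycin), and they give no tetracycline for ZHBTc4, so whether the lines were treated alike is not settled. The samples without LIF were also taken later after plating than those with it.

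Background was corrected with normexp (offset 50) on the mean signals and background medians in limma 3.58.1 (R 4.3.3), and each array was normalised by loess with weight 0 for control spots and for spots with an outlier flag. Flagged spots were left out and spots of one probe were averaged, which gave 42006 probes. A probe was kept when it was well above background in Cy3 on both arrays of at least 1 of the 9 groups, which left 31727. One model with a mean per group was fitted to all 18 arrays with lmFit, 17 comparisons were drawn from it, and eBayes moderated the variances (9 residual and 3.69 prior degrees of freedom). Calls needed a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold difference. Array pairs correlated with r between 0.743 and 0.996 over the probes, so no array ran in the opposite direction.

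The files do not pair the probes with genes. The probe identifiers are array design numbers, none of which (0) matched the table of mouse genes used here, and no genome or transcripts were used. The lists of genes fixed before the data were examined, the gene that the constructs carry and the markers to be followed were therefore not analysed here, nor was the alternative that averages the probes of a gene. In their place, probes past the threshold at 120 h in ZHBTc4 or in Oct4 were taken as sets and followed in the other lines, a choice made after seeing the data. Each set was tested with camera, with a preset correlation of 0.01 and with an estimated one, and Benjamini-Hochberg adjustment ran over 38 set tests, which also cover the Oct4-defined sets in ZHBTc4 and Oct4VP2. The rule for single features was to take those with the largest positive and negative difference past the threshold, and, for comparisons of 2 groups, without overlap between arrays. Because the features have no gene names, only 2 probes in each direction are given, for the difference of response between Oct4VP2 and Oct4.

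The arrays came from 5 slides scanned in 2 sessions, 12 arrays in the first and 6 in the second. The first session holds all Oct4VP2 arrays, the Oct4 arrays without LIF and replicate 1 of ZHBTc4 at 48 h and at 120 h. The second holds the remaining ZHBTc4 arrays and the Oct4 arrays with LIF. A session term was estimable from ZHBTc4 at 48 h and 120 h alone, where it coincides with the replicate number, and it passed an adjusted p of 0.05 in 2447 probes. In the Cy5 channel, which held the same reference RNA on every array, the same tests called between 10 and 166 probes per comparison, against 238 to 4464 in the ratios. The fit and the calls were tested on simulated data with 31727 probes and 200 changed ones. The simulation started from normalised values and added independent noise with each probe's own spread, without slide, session or replicate effects. Background correction, loess and the filter were thus not tested. With only 200 changed probes, the adjustment of p was also stricter than in the data. There, 7802 probes had an adjusted p under 0.05 for the 120 h change in Oct4VP2. The shares and the calls of unchanged probes that follow therefore hold for this setting and cannot be carried over to the data. For the 120 h change in Oct4VP2, 94% of the probes changed 3-fold and 97% of those changed 4-fold were called, 41.8% of those changed exactly 2-fold were called, and 2 unchanged probes were called. For the difference of response between Oct4VP2 and Oct4 the shares were 74.6%, 90.9% and 37.3%, with 4 unchanged probes called.

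The alternatives fixed before the data were examined were the Feature Extraction signals, the deposited value table, the Cy3 channel alone, Aquantile scaling, no filter on dim probes, slide as a random or fixed block, a replicate block, a fit to the compared groups alone and leaving out each array. Added after seeing the data were scan session as a block, each session alone, the ZHBTc4 pair with LIF averaged to 1 array, crossed replicate numbers in Oct4, and the change from 48 h to 120 h. That ZHBTc4 pair differed less in Cy3 (median absolute deviation 0.1 on the log2 scale) than the other pairs (0.14 to 0.26), and little more than its own reference channel (0.085). The channels were as close in the Oct4 pairs at 48 h (0.14 in Cy3, 0.13 in Cy5) and 120 h (0.14 and 0.15). Closeness to the reference channel is thus not particular to the ZHBTc4 pair. Whether it is 1 RNA sample measured on 2 arrays is not known, and it was kept as 2 arrays.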

Results

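Expression was profiled on 18 arrays carrying 60-base probes, each hybridised with the RNA of a mouse embryonic stem cell culture in Cy3 and a common mouse reference RNA in Cy5. Values are log2 ratios of sample over reference after background correction and loess within each array. The arrays covered 3 cell lines, which were compared. ZHBTc4 is an embryonic stem cell line whose oct4 expression comes from a transgene that tetracycline can shut off. The Oct4 line was derived from it by introducing an oct4 construct, and the Oct4VP2 line by introducing a construct that joins oct4 to the VP16 activation domain, a viral sequence that strongly activates transcription. Each line was sampled 24 h after plating with leukaemia inhibitory factor (LIF), the cytokine that keeps these cells undifferentiated in culture, and 48 h and 120 h after LIF was withdrawn, which made 9 groups with 2 arrays each. The series describes the replicates as independent clones. Between 62.8% and 75.2% of the probes on an array were well above background in Cy3, and the number of arrays limits the precision. The 2 arrays of a group correlated across probes with r from 0.962 to 0.996. The ZHBTc4 pair with LIF stood apart: its log2 ratios differed with an SD of 0.12, against 0.22 to 0.33 in the other 8 groups. The files do not pair the probes with genes, so the comparisons below are of probes, 31727 of which entered every test.

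The first question was how each line responded to the loss of LIF. In ZHBTc4, 2382 probes were higher and 2082 lower at 120 h without LIF than at 24 h with it, out of 31727 tested. In Oct4, 2199 were higher and 1759 lower. Oct4VP2 showed the smallest count, with 893 probes higher and 582 lower. At 48 h the counts were 593 higher and 751 lower in ZHBTc4, 443 higher and 433 lower in Oct4, and 300 higher and 270 lower in Oct4VP2. The ZHBTc4 balance at 48 h turned to 1367 higher and 1021 lower with the Feature Extraction signals, 987 and 718 with the deposited value table, and 816 and 794 with Cy3 alone. The Oct4 counts at 48 h, nearly even, became 1038 and 703 with the Feature Extraction signals, 739 and 471 with the value table and 496 and 286 with scan session as a block. For Oct4VP2 at 48 h, 254 were higher and 273 lower without replicate 1 of Oct4VP2 with LIF. The spread of the 120 h change over all probes, as an SD of log2 differences, was 0.754 in ZHBTc4, 0.724 in Oct4 and 0.48 in Oct4VP2. A probe was counted when limma's moderated test gave a Benjamini-Hochberg adjusted p under 0.05 and the change was at least 2-fold. With scan session as a block, the 120 h counts were 2351 higher and 1887 lower in ZHBTc4, 2144 and 1445 in Oct4, and 894 and 591 in Oct4VP2. Within the second session the ZHBTc4 counts were 2398 higher and 1965 lower at 120 h, and 359 higher and 428 lower at 48 h. That session held 1 ZHBTc4 array of each time without LIF, and the spread came only from the ZHBTc4 and Oct4 pairs with LIF, the first of which differed least of all pairs, so these counts are a weak check on session. Within the first, Oct4VP2 gave 866 higher and 567 lower at 120 h, and 264 and 254 at 48 h. The Oct4 arrays with LIF all lay in the second session and those without it in the first. The Oct4 count at 48 h rested on single arrays: the total of 876 became 392 (167 higher, 225 lower) without replicate 1 of Oct4 with LIF and 1468 (821 higher, 647 lower) without replicate 2. For ZHBTc4 at 48 h, the total of 1344 became 810 without replicate 1 of the 48 h group. LIF and the time since plating changed together in all these comparisons.

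**Figure D1:**
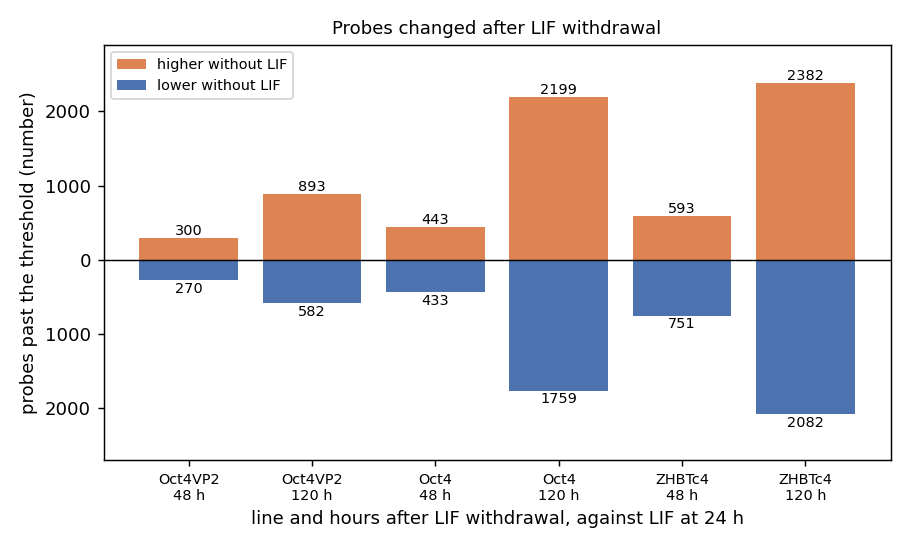
Bars give the number of probes past the threshold (adjusted p under 0.05 and at least 2-fold, limma) in each line 48 h and 120 h after LIF withdrawal, against 24 h with LIF, with higher probes drawn upwards and lower probes downwards from 0. Oct4VP2 has 893 higher and 582 lower probes at 120 h, against 2199 and 1759 in Oct4 and 2382 and 2082 in ZHBTc4.

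The next question was whether the lines changed in the same probes. Of the probes past the threshold at 120 h, 1306 were higher in both Oct4 and ZHBTc4, where independent lists would share 165.1, and 1129 were lower in both, where independent lists would share 115.4. Only 10 probes were past the threshold in opposite directions. Across all 31727 probes, which are not independent replicates, the 120 h changes of these lines correlated with r = 0.77, or 0.74 with scan session as a block. For Oct4VP2 and ZHBTc4 the shared calls were 444 higher and 276 lower, against 67 and 38.2 for independent lists, with r = 0.44 across probes, or 0.42 with the session block. For Oct4VP2 and Oct4 they were 385 higher and 243 lower, against 61.9 and 32.3, with r = 0.41, or 0.34 with the session block. None of these pairs of comparisons shares an array. At 120 h both Oct4 arrays shared a slide with replicate 1 of ZHBTc4, which could add to the r of 0.77. The Oct4 arrays with LIF shared a slide with the other ZHBTc4 array at 120 h, which could lower that r. The Oct4VP2 arrays of these changes shared no slide with those of the other lines. Slide was not tested apart here.

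Probes that changed in ZHBTc4 were then followed in the lines derived from it. The ZHBTc4-lower probes, the 2082 that were lower in ZHBTc4 at 120 h with a median log2 change of -1.42, had a median change of -1.08 in Oct4 and -0.33 in Oct4VP2. The ZHBTc4-higher probes, 2382 with a median change of 1.44 in ZHBTc4, had a median of 1.11 in Oct4 and 0.46 in Oct4VP2. Of the ZHBTc4-lower probes, 1129 fell past the threshold in Oct4 and 276 in Oct4VP2. Of the ZHBTc4-higher probes, 1306 rose in Oct4 and 444 in Oct4VP2. At 48 h these medians were -0.72 and 0.40 in ZHBTc4 and -0.29 and 0.24 in Oct4. In Oct4VP2 at 48 h they were 0.02 for the lower and 0.04 for the higher probes, and limma's camera test did not separate them from the other probes (adjusted p = 0.62 and 0.091). At 120 h camera with a preset correlation placed both sets apart from the other probes in Oct4VP2 (adjusted p = 4.4e-11 for the lower and 7.6e-23 for the higher probes). Those calls were lost with a correlation estimated for each set (adjusted p = 0.16 and adjusted p = 0.059). In Oct4 both sets kept the call with an estimated correlation (adjusted p = 0.039 for each). On each array, the mean log2 ratio of the 1306 probes higher in both ZHBTc4 and Oct4, set against ZHBTc4 with LIF, was 0.55 ± 0.26 in Oct4VP2 at 120 h, 1.84 ± 0.085 in Oct4 and 1.76 ± 0.042 in ZHBTc4 (SD, n = 2 each). For the 1129 probes lower in both, the means were -0.65 ± 0.0049, -1.98 ± 0.035 and -1.81 ± 0.17. These shared probes were chosen on the Oct4 and ZHBTc4 arrays, among them the ZHBTc4 arrays with LIF that serve as the baseline, so none of these values is independent of the choice. Against the same baseline, Oct4VP2 with LIF lay at -0.11 ± 0.057 for the higher and -0.17 ± 0.023 for the lower probes. Oct4 with LIF lay at 0.05 ± 0.25 and -0.24 ± 0.1, so an offset in the lower probes was not particular to Oct4VP2.

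**Figure D2:**
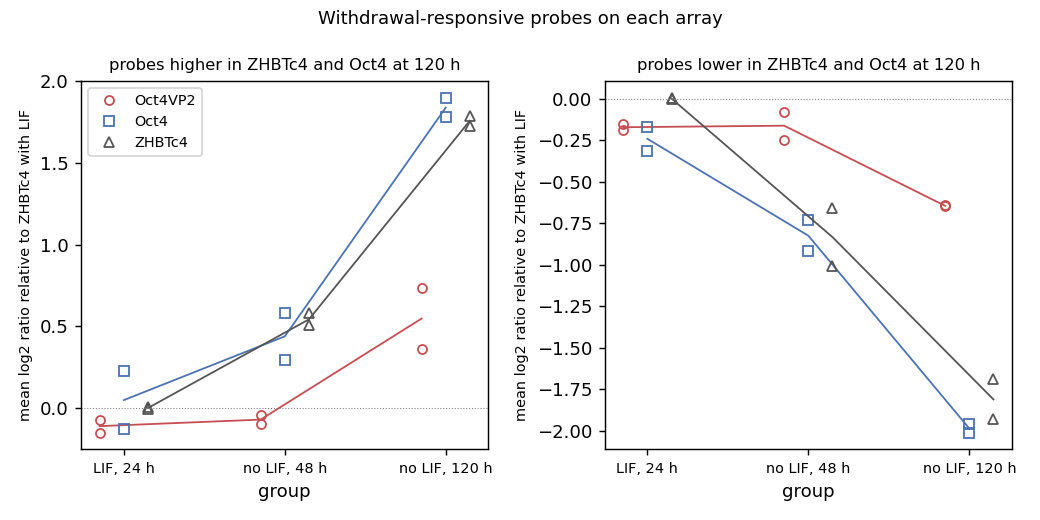
Each symbol is one array, placed by group on the horizontal axis, and its height is the mean log2 ratio of 1306 probes higher (left panel) or 1129 probes lower (right panel) in both ZHBTc4 and Oct4 at 120 h, relative to the mean of ZHBTc4 with LIF. Lines join the means of 2 arrays. The Oct4VP2 arrays at 120 h lie at 0.735 and 0.361 on the left and at -0.642 and -0.649 on the right, between the arrays with LIF and the other lines at 120 h.

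The difference between the responses was tested directly. The 120 h change differed between Oct4VP2 and Oct4 in 3368 probes, of which 1671 had the more positive change in Oct4VP2 and 1697 the more negative. Against ZHBTc4 the change in Oct4VP2 differed in 3410 probes, 1809 more positive and 1601 more negative, or 2222 and 2461 with the Feature Extraction signals and 1563 and 1684 with the value table. Single arrays turned both balances. Against Oct4 the counts were 1593 more positive and 1400 more negative without replicate 1 of Oct4 with LIF, 1780 and 1676 without replicate 2 of Oct4VP2 with LIF, and at 120 h 1622 and 1520 without replicate 2 of Oct4VP2 and 1641 and 1628 without replicate 2 of Oct4. Against ZHBTc4 they were 1717 and 1740 without replicate 1 of ZHBTc4 at 120 h. The ZHBTc4-lower probes fell less in Oct4VP2 than in Oct4, with a median difference of 0.75 between the changes, and 721 of them passed the threshold in that direction against 31 in the other. The ZHBTc4-higher probes rose less in Oct4VP2, with a median difference of -0.66, and 698 of them passed in that direction against 51. Camera with a preset correlation gave adjusted p = 8.3e-28 for the lower and adjusted p = 1.1e-14 for the higher probes. With an estimated correlation neither call held after adjustment (adjusted p = 0.054 and adjusted p = 0.12). Probes past the threshold in Oct4 at 120 h were followed against ZHBTc4. The 1759 lower ones had a median difference of 0.91 between the Oct4VP2 and ZHBTc4 changes, with 738 past the threshold in that direction against 20. The 2199 higher ones had a median of -0.69, with 695 against 40. With an estimated correlation camera called the lower set and not the higher one (adjusted p = 0.043 and 0.089). With scan session as a block the counts were 1507 more positive and 1842 more negative against Oct4, and 1729 and 1736 against ZHBTc4. ZHBTc4-lower and ZHBTc4-higher sets chosen anew in that fit (1887 and 2351 probes) had medians of 0.62 and -0.69 against Oct4.

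The 2 probes with the most positive and the 2 with the most negative difference between the 120 h changes of Oct4VP2 and Oct4 are given with their sequences. The first pair fell in Oct4 and rose in Oct4VP2. Probe Z00041731-1 (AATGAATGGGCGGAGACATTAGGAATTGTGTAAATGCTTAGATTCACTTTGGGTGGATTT) had a log2 ratio of 4.27 ± 0.18 in Oct4 with LIF and 0.79 ± 0.13 at 120 h without it (SD, n = 2). In Oct4VP2 it went from 2.92 ± 0.02 to 4.22 ± 0.56, and in ZHBTc4 from 3.84 ± 0.082 to 2.27 ± 0.38. The difference between the Oct4VP2 and Oct4 changes was 4.78 (SE 0.36, limma adjusted p = 1.4e-05). Probe Z00074099-1 (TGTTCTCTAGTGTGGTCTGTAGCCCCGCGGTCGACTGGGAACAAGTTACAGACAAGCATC) went from 3.22 ± 0.12 to -0.23 ± 0.16 in Oct4, from 3.29 ± 0.57 to 4.37 ± 0.2 in Oct4VP2 and from 2.43 ± 0.034 to 0.63 ± 0.34 in ZHBTc4, a difference of 4.53 between Oct4VP2 and Oct4 (SE 0.31, limma adjusted p = 8.6e-06). The second pair rose in Oct4 and ZHBTc4. Probe Z00042006-1 (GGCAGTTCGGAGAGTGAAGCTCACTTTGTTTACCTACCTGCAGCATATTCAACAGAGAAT) went from -4.29 ± 0.48 to 1.39 ± 0.18 in Oct4 and from -3.86 ± 0.053 to -0.85 ± 0.59 in ZHBTc4. In Oct4VP2 it stood at -3.75 ± 0.016 with LIF and -3.85 ± 0.58 at 120 h (limma adjusted p = 0.84), and the difference from Oct4 was -5.78 (SE 0.4, limma adjusted p = 8.6e-06). Probe Z00075208-1 (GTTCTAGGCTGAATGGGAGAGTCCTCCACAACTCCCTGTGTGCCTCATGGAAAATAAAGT) rose from -0.80 ± 1.2 to 3.85 ± 0.098 in Oct4 and from 0.80 ± 0.05 to 3.67 ± 0.65 in ZHBTc4, and fell from 0.66 ± 0.38 to -1.13 ± 1.2 in Oct4VP2. Its difference of -6.44 had the widest standard error of the 4 (SE 0.82, limma adjusted p = 0.00023). All 4 probes were well above background on both arrays of every group.

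**Figure D3:**
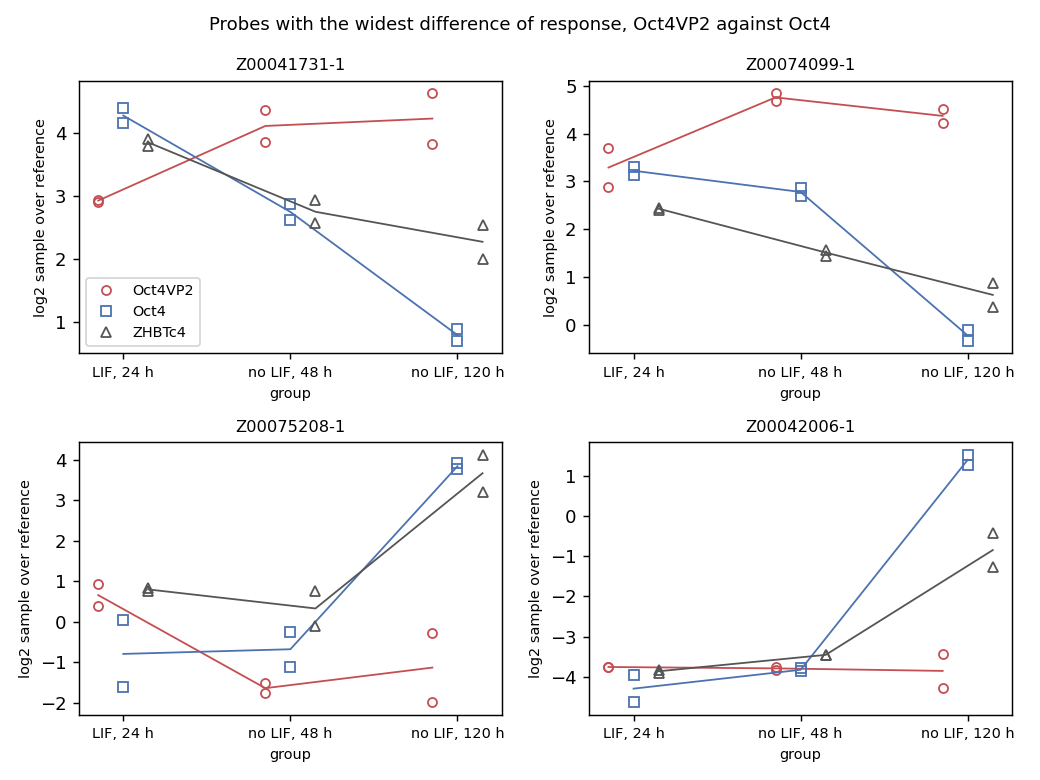
Symbols give the log2 ratio of sample over reference on each of 18 arrays for 4 probes, by line and group, and lines join the means of 2 arrays. At 120 h without LIF, Z00041731-1 and Z00074099-1 are higher in both Oct4VP2 arrays than in any Oct4 or ZHBTc4 array, and Z00075208-1 and Z00042006-1 are lower.

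The lines were also compared with each other at each time. Oct4VP2 and Oct4 differed in 1299 probes with LIF (710 higher in Oct4VP2, 589 lower), in 1938 at 48 h (1046 higher, 892 lower) and in 3225 at 120 h (1633 higher, 1592 lower). With LIF the balance rested on 1 array: without replicate 1 of Oct4, 632 were higher and 737 lower. At 120 h it turned to 1850 higher and 1892 lower without replicate 1 of Oct4VP2, and to 1572 and 1610 without replicate 1 of Oct4. The difference with LIF correlated across probes with that at 48 h (r = 0.6) and less with that at 120 h (r = 0.3). The Oct4VP2 arrays with LIF and at 48 h lay on the same slide, which could add to the first r. Of the probes that differed with LIF, 694 also differed in the same direction at 48 h, where independent lists would share 23.4 higher and 16.6 lower. At 120 h the ZHBTc4-lower probes were higher in Oct4VP2 than in Oct4 by a median log2 of 0.82 and the ZHBTc4-higher probes lower, with a median of -0.80 (camera adjusted p = 1.5e-37 and 8.2e-30, and adjusted p = 0.043 and 0.045 with an estimated correlation). With LIF the medians were 0.09 and -0.13. Camera with a preset correlation called only the second of these (adjusted p = 0.16 and 0.00016), and that call was lost with an estimated correlation (adjusted p = 0.39). With LIF, the Oct4VP2 arrays lay in the first scan session and the Oct4 arrays in the second, and with session as a block 1154 probes were higher and 666 lower. Both lines lay in the first session at 48 h and 120 h, and that session alone gave 1013 higher and 862 lower at 48 h and 1616 higher and 1574 lower at 120 h.

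Against ZHBTc4, Oct4VP2 differed in 1072 probes with LIF (379 higher, 693 lower), in 1868 at 48 h (1022 higher, 846 lower) and in 3159 at 120 h (1467 higher, 1692 lower). With LIF these lines lay in different sessions and the direction depended on the processing: with session as a block 499 were higher and 389 lower, and with the Feature Extraction signals 1355 were higher and 984 lower. At 120 h the Feature Extraction signals gave 2954 higher and 2507 lower, and the deposited value table gave 2055 and 1686, so the direction turned there too. Without replicate 2 of ZHBTc4 at 120 h, 1531 were higher and 1529 lower, and without replicate 1 of ZHBTc4 at 48 h, 808 were higher and 818 lower. Within the first session, which held 1 ZHBTc4 array of each time without LIF, 1126 were higher and 830 lower at 48 h, and 1490 were higher and 1487 lower at 120 h. Oct4 and ZHBTc4 differed least. The counts were 688 with LIF (166 higher in Oct4, 522 lower), 238 at 48 h (116 higher, 122 lower) and 1250 at 120 h (517 higher, 733 lower). With the Feature Extraction signals 256 were higher and 177 lower at 48 h. With session as a block the counts were 172 higher and 551 lower with LIF, 166 and 115 at 48 h, and 503 and 600 at 120 h. Both lines with LIF lay in the second session, which alone gave 159 higher and 549 lower, and the first session alone gave 53 and 38 at 48 h and 416 and 506 at 120 h. Leaving out replicate 1 of ZHBTc4 with LIF lowered the count with LIF to 447. At 48 h, leaving out replicate 2 of Oct4 or replicate 2 of ZHBTc4 lowered the count and kept the balance nearly even. Leaving out replicate 1 of ZHBTc4 at 48 h turned the balance towards probes lower in Oct4.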

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

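The tests of scan session, of the state with LIF and of the Oct4 labels, and the set medians themselves, were chosen only after the result was seen. The 120 h change differed between Oct4VP2 and Oct4 in 3368 probes and between Oct4VP2 and ZHBTc4 in 3410, each by a test of the difference itself. The same moderated test gave differences between Oct4VP2 and Oct4 of 4.78 for Z00041731-1, 4.53 for Z00074099-1, -6.44 for Z00075208-1 and -5.78 for Z00042006-1. The ZHBTc4-lower and ZHBTc4-higher probes had median differences of 0.75 and -0.66 between these lines, which camera called with a preset correlation but not with an estimated one (adjusted p = 0.054 and 0.12). Against ZHBTc4, the probes lower and higher in Oct4 at 120 h had median differences of 0.91 and -0.69. There, camera with an estimated correlation called the lower set but not the higher one (adjusted p = 0.043 and 0.089).

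The smaller response of Oct4VP2 at 120 h was weighed against technical explanations. Within the first session the change from 48 h to 120 h still differed between Oct4VP2 and Oct4 by a median of 0.4 in the ZHBTc4-lower and -0.44 in the ZHBTc4-higher probes. Camera called both sets with the preset correlation (p = 7.2e-14 and 2.2e-13) and neither with an estimated one (p = 0.057 and 0.11), so the sets alone do not decide. Single probes also differed in that step, 934 with the more positive change in Oct4VP2 and 869 with the more negative, which does not say which line changed less. In that session the step itself gave 227 probes higher and 213 lower in Oct4VP2, against 1824 and 1532 in Oct4. These smaller counts in Oct4VP2 argue against the difference between scan sessions as the whole cause. Background correction, dye normalisation and the reference channel are argued against too: the median of the lower set was 0.82 with the Feature Extraction signals and 0.76 with Cy3 alone. The lower set was chosen anew under each processing (3293 and 2334 probes), so the probes are not the same ones. A displacement of Oct4VP2 towards the withdrawn state already with LIF would place the ZHBTc4-lower probes lower than in Oct4, and their median difference there was 0.09, or 0.35 with session as a block. Against ZHBTc4 with LIF, probes lower in Oct4 at 120 h had a median of -0.1, the direction of such a displacement (camera adjusted p = 0.021, or 0.65 with an estimated correlation). Those higher in Oct4 had a median of -0.03, the other direction (adjusted p = 0.41). With slide as a random block, sets chosen anew in that fit (2070 and 2364 probes) had medians of 0.67 and -0.65, and the count was 3003. These groups lie on different slides and this block cannot remove a shift shared by a whole slide, so the slide stays open. The cells plated and the construct itself, which the design names, stay open too and were not tested apart. So does a difference of line or treatment in the Oct4 arrays with LIF, described in other terms in the labels. These arrays are the baseline of the Oct4 change at 120 h, but do not enter the change from 48 h to 120 h.

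The difference between Oct4VP2 and Oct4 with LIF lies across the scan sessions. It correlated across probes with the 48 h difference, which lies within the first session and shares no array with it, at r = 0.6. The Oct4VP2 arrays of both differences lie on the same slide, so a shift of that slide could add to this r. With the 120 h difference, also within the first session and without a shared slide, r was 0.3. These correlations argue against session as the whole cause, and slide was not tested apart. With session as a block the count went from 1299 to 1820. That term comes from ZHBTc4 alone, where it coincides with the replicate number, so the rise does not decide about session. Whether the Oct4 arrays with LIF, described in other terms in the labels, may hold another line cannot be told apart from a change of the line difference over time. The difference of Oct4 from ZHBTc4 with LIF correlated with those at 48 h and 120 h with r = 0.46 and r = 0.32, and with session as a block only with r = 0.31 and r = 0.24.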

How the results depend on the processing

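With the Feature Extraction signals, to which no offset is added, 16 of 17 counts rose by over 1.5 times. Withdrawal at 48 h and 120 h gave 958 and 3268 probes in Oct4VP2, 1741 and 7108 in Oct4, and 2388 and 7411 in ZHBTc4. Oct4VP2 against Oct4 gave 2882 with LIF, 3232 at 48 h and 5944 at 120 h, Oct4VP2 against ZHBTc4 2339, 3434 and 5461, Oct4 against ZHBTc4 1380, 433 and 2727, and the difference of response against Oct4 5302. The deposited value table, with 19438 of the probes, gave 1996 for Oct4VP2 against Oct4 with LIF, and 1041 with LIF and 1925 at 120 h for Oct4 against ZHBTc4. The cause of these rises was not tested. The share of higher probes went from 44.1% to 57.2% and 57.9% (Feature Extraction, value table) for ZHBTc4 at 48 h, from 35.4% to 57.9% and 57.2% for Oct4VP2 against ZHBTc4 with LIF, from 24.1% to 45.4% and 45.6% for Oct4 against ZHBTc4 with LIF, and from 48.7% to 59.1% and 59.5% for these lines at 48 h. For Oct4 at 48 h it went from 50.6% to 59.6% and 61.1%, and to 63.4% with session as a block. In 11 of 17 counts the larger side turned under at least 1 alternative. Oct4 against ZHBTc4 at 48 h, 238 probes, became 155 with slide as a random block, 86 in a fit to the compared groups alone, which has fewer arrays, and 91 within the first session. ZHBTc4 at 48 h became 787 within the second session, with 1 array at 48 h. With an estimated correlation, neither set was called for the difference of response after adjustment (medians 0.75 and -0.66, adjusted p = 0.054 and 0.12), and the ZHBTc4-higher probes not before it either (p = 0.061).

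Leaving out single arrays moved Oct4 at 48 h between 392 and 1468, ZHBTc4 at 48 h between 810 and 1786, and Oct4 against ZHBTc4 between 447 and 872 with LIF and between 78 and 217 at 48 h. An arm left with 1 array was assumed to vary like the other groups. The other 13 counts stayed within 1.5 times. Cy3 alone, no filter on dim probes, session as a block and the averaged ZHBTc4 pair kept every count they gave within 1.5 times. Slide as a fixed block was estimable for 3 comparisons. In this design it was the same fit as session as a block and gave the same counts (597, 3589 and 1103), so it is no separate check on slide. Aquantile leaves ratios as they are and tests nothing. The 4 named probes kept their direction and call under every alternative that gave them a value. They were chosen on these same arrays as the widest differences, so this is a weak check and their sizes may be overstated.

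The replicate numbers were not taken to pair the arrays. Differences between replicates 1 and 2 correlated across probes within Oct4VP2 (r = 0.29 to 0.52), between 48 h and 120 h in Oct4 (r = 0.22) and most between 48 h and 120 h in ZHBTc4 (r = 0.7), where the number coincides with slide and session. They did not between ZHBTc4 with and without LIF (r = -0.019 and -0.037). Between groups of different lines, which no clone pairs, r ranged from -0.25 to 0.2, so the values of 0.22 and 0.29 lie near that range. The other values in Oct4VP2 lie well outside it. They were 0.5 between 48 h and 120 h, on different slides, and 0.52 between LIF and 48 h, on the same slide. With 2 numbers this leaves open whether they pair the arrays. As a replicate block they moved the difference of response against Oct4 from 3368 to 3541 probes and withdrawal at 120 h in Oct4VP2 from 1475 to 1511, and no count by over 1.14 times. In Oct4, the differences with LIF and at 48 h correlated with r = -0.23, and crossing the numbers gave 962 probes at 48 h. The gene lists and the mean over the probes of a gene were not run, since no probe has a gene name. Probes near background are compressed towards no change.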

Other observations

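The later part of the response, from 48 h to 120 h without LIF, was set apart after seeing the data. In Oct4, 1843 probes were higher and 1542 lower at 120 h than at 48 h, and in Oct4VP2 251 were higher and 235 lower. The change was more positive in Oct4VP2 than in Oct4 in 948 probes and more negative in 907. The arrays involved all lie in the first session, and a fit to that session alone gave 934 and 869.

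Oct4VP2 at 48 h changed in 570 probes, and its change correlated across probes with the 48 h changes of ZHBTc4 (r = 0.33) and Oct4 (r = 0.32). With ZHBTc4 at 48 h it shared 100 higher and 98 lower calls, where independent lists would share 5.6 and 6.4, and 6 were opposite. With the 120 h change of ZHBTc4 it was hardly correlated (r = 0.016): 62 higher and 73 lower calls were shared, where independent lists would share 22.5 and 17.7, and 98 were opposite. Its 120 h change was closer to the 48 h change of ZHBTc4 (r = 0.57).

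One hypothesis is that Oct4VP2 at 120 h may resemble an earlier stage of the course seen in ZHBTc4. Probes changed in ZHBTc4 at 120 h were split into early ones, changed by at least 0.5 on the log2 scale in the same direction by 48 h, and late ones, changed by under 0.2. The bounds set before this test were that a plain delay would leave late probes with under 0.1 of their ZHBTc4 change and early probes with over 0.4, and that late probes with at least 0.2 would speak against it. In Oct4VP2 at 120 h the late probes kept 0.1 (262 lower) and 0.11 (548 higher) of it, and the early probes kept 0.28 (1343 lower) and 0.5 (1012 higher). In Oct4 at 120 h the late probes kept 0.8 and 0.68. The late probes thus lay between their 2 bounds, the early higher probes met the bound for a delay and the early lower probes missed it, so the test did not settle the hypothesis.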
